A study of Mus musculus with 6 samples.

How the data were processed

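Total RNA from sorted EpCAM-positive, CD45-negative colonic epithelial cells was turned into biotin-labelled cRNA from 6 µg of RNA and hybridised to Affymetrix arrays, per the labels' protocols. The 6 samples form 2 groups of 3, male BALB/c mice re-fed for 24 h after a 36 h fast without or with antibiotics, and the labels call the samples of a group biological replicates without saying how many mice each holds. Groups and replicate numbers were taken from the sample titles. The deposited table holds log2 expression values of 35557 probe sets on all 6 arrays, made by the authors with RMA (background correction, quantile normalisation and summary of probes into probe sets), per the submitters' processing notes; its version and the annotation used are not given in the sources used here.

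The deposited values do not come from a single run of RMA, as far as the values tell. Arrays normalised together take their probe values from 1 shared distribution, so some probe sets receive the very same number on several arrays. Re-fed replicates 2 and 3 and antibiotics replicates 1 and 2 shared 372 to 435 distinct values per pair and are called the common run. Re-fed replicate 1 shared 154 to 198 values with them. Antibiotics replicate 3 shared 42 to 67 values with the others and held 10829 distinct values, where each other array held at least 34568. Fewer distinct values leave fewer to share, so its low counts alone are weak evidence of a separate run. Array medians were 5.87, 6.06 and 6.08 in re-fed replicates 1 to 3 and 6.17, 6.16 and 5.63 in antibiotics replicates 1 to 3. Each array outside the common run was taken to stand alone in its run. A fit with the run as a block then equals the fit within the 4 arrays of the common run, which is given beside the values over 6 arrays. This grouping was inferred from the values, not from a label.

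Quantile normalisation over the 23410 probe sets with a gene in the platform table was applied to the deposited values, since their medians differ. It had been listed as an alternative before the data were examined, with the deposited scaling as the planned setting, and the change was made when the medians had been seen and before any test was run. Of the 35557 probe sets, 21789 named exactly 1 gene, 1621 named several and 12147 were unnamed here. Control probe sets are not marked in the table, and probe sets with a gene were taken as free of them. Of the 21789, 21698 were matched by Entrez identifier to a RefSeq table of the mouse assembly GRCm38.p6, used for names alone, and 0 symbols changed. No coordinates are printed, because no build is named for the table. Each of 19938 genes was represented by its own probe set with the highest mean over 6 arrays. Pcna, 1 of the named genes, has 2 probe sets, and both gave 0.27. Genes with a mean under the 40th percentile of probe sets (5.81) were left out as dim, since RMA gives no detection call, and 12071 remained. The number of arrays limits the precision of every value.

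Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05), with no block. Gene lists were tested with camera at a preset correlation of 0.01 where at least 5 genes were tested, adjusted over the lists, and again with an estimated correlation and with fry. Errors are SDs over 3 arrays or moderated standard errors from limma. Fold changes are 2 to the power of the log2 difference, given as the higher over the lower level. Tests, groups, lists, alternatives and the naming rule were fixed before the data were examined, apart from the scaling above and the additions named as chosen later.

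The rule for named genes had 3 parts. It took up to 8 genes per direction with the largest difference among those past the threshold whose groups do not overlap, up to 3 members of each list with the smallest unadjusted p, and a few genes whatever their values (Epcam, Ptprc, Mki67, Pcna, Ccnd1, Slc16a1 and 1 more that was not analysed here). The 26 lists covered S-phase and DNA replication, G2/M and mitosis, ribosome biogenesis and Myc targets, crypt-base stem cells and Wnt targets, goblet cells, absorptive colonocytes, enteroendocrine cells, tuft cells, host defence that responds to microbes, interferon-stimulated genes, MHC class II presentation, glycolysis and lactate handling, fatty acid oxidation with ketogenesis and PPAR targets, cholesterol biosynthesis, the amino acid response with serine synthesis, chaperones of the endoplasmic reticulum, p53 targets and apoptosis, the circadian clock, xenobiotic metabolism, immediate-early genes, T cells and intraepithelial lymphocytes, B and plasma cells, myeloid cells, stroma and endothelium, pan-epithelial genes, and small-intestinal enterocytes and Paneth cells. They were written from general knowledge, not chosen on these samples. Members that were dim or had no probe set of their own here were not analysed.

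The procedure was tested on simulated data for the same 3 against 3 comparison of 12071 genes, 10 times with 200 changed genes. It recovered 41.2% of genes changed by 0.5 on the log2 scale, 99.1% of those changed by 1 and 100% of those changed by 2, with 6.59% false among all calls. A list of 30 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 10 of 10 simulations, and an unchanged list in 0. The list calls on the real arrays use an adjusted p, which is stricter. Simulated genes were independent, which real genes are not. Their noise was normal, drawn with limma's moderated variances, and no effect of separate runs was added. The recovered shares also hold only for 200 planted changes, which loosen the adjusted cutoff. In the real comparison 7 genes passed. Genes that differed by more than 1, such as Sptssb (-1.86, limma, adjusted p = 0.0584) and Dbp (-1.61, adjusted p = 0.0779), did not. The alternatives were a replicate block, each array left out in turn, no filter or a stricter one (60th percentile), centring on array medians, cyclic loess, eBayes with an intensity trend and robust settings, array weights, the mean of a gene's probe sets, all probe sets tested on their own, other thresholds and other list tests. The deposited scaling, first planned as the main setting, was run as an alternative too. Added after seeing the data were centring on the median of all annotated probe sets and the 4 arrays of the common run with either scaling.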

Results

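Gene expression was measured on 6 Affymetrix arrays, 1 per sample, in epithelial cells of the mouse colon. The cells carried EpCAM, a surface protein of epithelia, and lacked CD45, the leukocyte antigen encoded by Ptprc. They came from male BALB/c mice aged 6 weeks that had fasted for 36 h and then had food again for 24 h. Of the samples, 3 came from mice re-fed without antibiotics (re-fed) and 3 from re-fed mice treated with antibiotics, whose names are not given in the sources used here. The comparison asks which genes of the re-fed colonic epithelium differ when antibiotics are given, a setting studied for the part that gut bacteria play in epithelial proliferation after a fast. After quantile normalisation, 12071 genes lay above the floor for dim signal (5.81 on the log2 scale) and were tested. Every difference below is a log2 difference, antibiotics minus re-fed. The deposited values of 4 arrays (re-fed replicates 2 and 3, antibiotics replicates 1 and 2) bear the mark of 1 common normalisation run, and the difference within these 4 arrays is given beside that over 6.

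Retnlb, which encodes a resistin-like protein of goblet cells known to depend on gut bacteria, fell with antibiotics from 8.87 ± 0.56 to 7.04 ± 0.15 (log2 expression, SD, n = 3 per group), a 3.55-fold lower level. Slc7a9, the light subunit of the epithelial transporter for cystine and dibasic amino acids, was the 1 gene that rose, from 6.58 ± 0.029 to 7.78 ± 0.12, or 2.29-fold. The aldo-keto reductases Akr1b8 and Akr1b10 fell by 1.36 (SE 0.13) and by 1.05 (SE 0.12). Abcb1a, the drug efflux pump P-glycoprotein, fell by 0.94 (SE 0.12), a 1.92-fold lower level. Tns4, a tensin of focal adhesions, fell by 0.93 (SE 0.12), and Cpne2, a copine that binds phospholipids in a calcium-dependent way, fell by 0.87 (SE 0.11).

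These were the 7 genes that passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, 1 higher and 6 lower. The adjusted p was 0.00875 for Slc7a9 and Akr1b8, 0.0243 for Akr1b10 and 0.0441 for the other 4 genes. In each of the 7, the 3 values with antibiotics did not overlap the 3 without. Such a separation held for 2362 genes, 19.6% of those tested, where chance gives 10%. At an unadjusted p under 0.05 there were 1524 genes, 640 higher and 884 lower, where chance gives 604. With the deposited scaling, first planned as the main setting, 465 genes had such a p, so the excess did not hold there. The other alternatives that keep all 6 arrays gave from 1265, with the stricter filter, to 3531, with array weights. After quantile normalisation, the other divisions of the 6 arrays into 3 and 3 gave 176 to 1075 genes at an unadjusted p under 0.05. Each of them sets 2 arrays of a group against 2 of the other, so none is free of treatment. Their counts cannot show what a grouping without treatment gives. Within the common run 54 genes passed, 13 higher and 41 lower, and all 7 were among them with the same sign. Their differences there were -2.21 for Retnlb, 1.22 for Slc7a9, -1.48 for Akr1b8, -1.01 for Akr1b10, -0.82 for Abcb1a, -0.95 for Tns4 and -0.85 for Cpne2. The count was 5, 3 or 11 without re-fed replicate 1, 2 or 3, and 0, 4 or 2 without antibiotics replicate 1, 2 or 3. In the limma fit with 0 genes, 1040 had an unadjusted p under 0.05. Slc7a9 (1.12) and Akr1b8 (-1.27) lost their call only without antibiotics replicate 1, where both had an adjusted p of 0.067. The call of Akr1b10 was lost without re-fed replicate 1 or any antibiotics replicate, that of Retnlb without any array but re-fed replicate 1, that of Abcb1a without any array but antibiotics replicate 2, and those of Tns4 and Cpne2 without any 1 array. In those fits the differences came no closer to 0 than -1.02 for Akr1b10, -1.64 for Retnlb, -0.85 for Abcb1a, -0.83 for Tns4 and -0.81 for Cpne2. Over the settings that keep all 6 arrays, the count lay between 2, with no filter on dim probe sets, and 1169, with array weights. Akr1b8 and Akr1b10 are close paralogs, and signal shared between their probes was not examined.

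**Figure D1:**
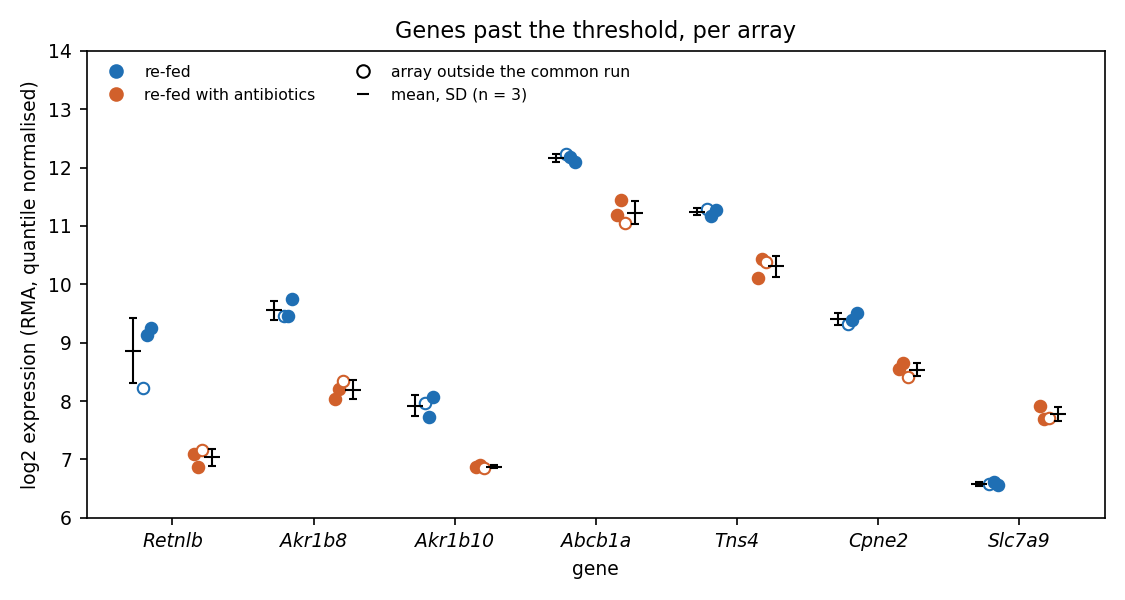
The plot shows log2 expression (vertical axis) of the 7 genes that passed the test (horizontal axis) on each array, re-fed in blue and re-fed with antibiotics in orange, with open symbols for the 2 arrays outside the common run and black bars for the mean and SD of 3 arrays. The groups do not overlap in any of the 7 genes, and Retnlb lies at 8.87 ± 0.56 without and 7.04 ± 0.15 with antibiotics.

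Of the 26 gene lists fixed in advance, 24 had at least 5 genes tested, and camera with a preset correlation called 10 of them, 5 higher and 5 lower with antibiotics. With a correlation estimated from the data, camera called 0, with 1 list at an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance, called 0, with 3 such lists. Within the common run 8 lists were called, 6 of them among the 10, and 0 with an estimated correlation. List calls given below for other settings rest on the preset correlation. Of the 10 ways to divide the 6 arrays into 3 and 3, another also called 10 lists. It sets antibiotics replicates 1 and 2 against re-fed replicates 2 and 3 as the true division does, and exchanges the 2 arrays outside the common run. The list of fatty acid oxidation was the 1 called list with its smallest p in the true division.

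Genes of fatty acid oxidation, ketogenesis and the PPAR response lay lower with antibiotics. Cpt1a, which brings long-chain fatty acids into mitochondria, stood at 10.79 ± 0.16 without and 10.12 ± 0.13 with antibiotics (-0.67, SE 0.12, adjusted p = 0.0868). The lipid droplet protein Plin2 differed by -0.48 (SE 0.10) and the dehydrogenase Acadl by -0.47 (SE 0.10). The median over 23 genes was -0.26, with 20 below 0 and 3 above (camera, adjusted p = 3.9e-07, and adjusted p = 0.724 with an estimated correlation). No member passed over all genes, and 7 passed when adjusted over the list alone, all lower. The median was -0.27 in the common run (adjusted p = 1.67e-06, and adjusted p = 0.68 with an estimated correlation), and the list stayed called without any 1 array.

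Among genes of glycolysis and lactate handling, Hk2, a hexokinase, stood at 11.01 ± 0.15 without and 10.25 ± 0.15 with antibiotics (-0.76, SE 0.12, adjusted p = 0.0692). It was the 1 gene of the list that passed when adjusted over the list alone. Within the common run 2 members passed, Hk2 lower (-0.76, adjusted p = 0.0404) and, named after its values were seen, the lactate exporter Slc16a3 higher (0.73, adjusted p = 0.0371). Over 6 arrays Slc16a3 differed by 0.39 (SE 0.19, adjusted p = 0.437). The monocarboxylate transporter Slc5a8 differed by -0.28 (SE 0.11), the kinase Pdk1 by 0.27 (SE 0.12) and the lactate transporter Slc16a1 by -0.23 (SE 0.11, adjusted p = 0.441). The 18 genes tested went both ways, 9 above and 9 below 0, and the list was not called (adjusted p = 0.881). Its median was 0.01 (0.0127) and 0.086 in the common run, its mean over 6 arrays was -0.021, and camera placed it lower.

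The list of host defence genes that respond to microbes was called lower with antibiotics, with 14 genes below 0 and 9 above. Its arrays overlapped between the groups. The list's deviation from the 6-array mean was -0.083 in re-fed replicate 1, against -0.045 and 0.018 in antibiotics replicates 1 and 2. Besides Retnlb, Il18, a cytokine of the epithelium, stood at 9.78 ± 0.18 and 9.13 ± 0.05 (-0.65, SE 0.12, adjusted p = 0.0868), and Ang4, an antimicrobial ribonuclease, at 6.82 ± 0.06 and 6.20 ± 0.22 (-0.62, SE 0.13, adjusted p = 0.117). Of 23 genes tested, 1 fell over all genes and 22 did not pass, and 3 passed when adjusted over the list alone, all lower. The median was -0.16 (camera, adjusted p = 0.0221, and adjusted p = 0.724 with an estimated correlation) and -0.23 in the common run (adjusted p = 0.00322, and adjusted p = 0.68 with an estimated correlation). The call was lost without re-fed replicate 2 (-0.26, adjusted p = 0.169), without antibiotics replicate 3 (-0.12, adjusted p = 0.0772) and with the stricter filter on dim probe sets (-0.16, adjusted p = 0.186).

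Goblet cell genes, which share Retnlb and Ang4 with the host defence list, had a median of -0.21 over 21 genes, 16 of them below 0. Spink4 stood at 10.91 ± 0.09 without and 10.32 ± 0.55 with antibiotics (-0.59, SE 0.23). Over all genes 1 member fell, and 2 passed when adjusted over the list alone, both lower. Camera called the list (adjusted p = 0.00122), but not with an estimated correlation (adjusted p = 0.724), and the median was -0.26 in the common run (adjusted p = 9.48e-07, and adjusted p = 0.68 with an estimated correlation). The call was lost without antibiotics replicate 2 (-0.089, adjusted p = 0.171).

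Absorptive colonocyte genes had a median of -0.085 over 28 genes, 18 below and 10 above 0. The sodium channel subunit Scnn1a differed by -0.57 (SE 0.12), the sodium/proton exchanger Slc9a3 by -0.63 (SE 0.15) and the membrane protein Emp1 by -0.88 (SE 0.23). No member passed over all genes, while 8 lower and 1 higher passed when adjusted over the list alone. The higher one, named after its values were seen, was Guca2b, the precursor of uroguanylin (0.52, SE 0.14). Within the common run 1 member passed over all genes, Slc37a2 (-1.21, adjusted p = 0.0361), also named after its values were seen. Over 6 arrays it differed by -0.65 (SE 0.30, adjusted p = 0.41). Camera called the list lower (adjusted p = 0.0123, and adjusted p = 0.724 with an estimated correlation), with a median of -0.027 in the common run (adjusted p = 0.0352, and adjusted p = 0.727 with an estimated correlation). The 6-array median lay at percentile 11.35 of 10000 random lists matched on mean expression, whose 5% point was -0.11. The call was lost without re-fed replicate 3 (-0.025), antibiotics replicate 1 (-0.056) or antibiotics replicate 3 (-0.023), at adjusted p from 0.0611 to 0.177.

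Genes of ribosome biogenesis and Myc targets lay higher with antibiotics. The nucleolar protein Nop56 stood at 8.42 ± 0.20 without and 9.06 ± 0.17 with antibiotics (0.64, SE 0.14, adjusted p = 0.127), the spermidine synthase Srm differed by 0.70 (SE 0.16) and the RNA polymerase I subunit Polr1b by 0.56 (SE 0.14). The median was 0.27 over 30 genes, 27 of them above 0 (camera, adjusted p = 3.06e-08, and adjusted p = 0.724 with an estimated correlation). No member passed over all genes, and 7 passed when adjusted over the list alone, all higher. The median in the common run was also 0.27 (adjusted p = 4.26e-06, and adjusted p = 0.68 with an estimated correlation), and the list stayed called without any 1 array.

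The 2 lists of the cell cycle were called higher over 6 arrays, but not within the common run and not with an estimated correlation (adjusted p = 0.724 for both). Of S-phase genes, the replicative helicase subunits Mcm5 and Mcm7 differed by 0.67 (SE 0.17) and 0.55 (SE 0.16), and Uhrf1 by 0.36 (SE 0.14). Of G2/M genes, cyclin A2 (Ccna2) differed by 0.63 (SE 0.20), Cenpa by 0.36 (SE 0.14) and Cdc20 by 0.37 (SE 0.15). The proliferation marker Mki67 stood at 7.82 ± 0.27 without and 8.32 ± 0.45 with antibiotics (0.50, SE 0.22, adjusted p = 0.387) and differed by 0.11 in the common run. Pcna differed by 0.27 (SE 0.15, adjusted p = 0.481) and Ccnd1 by 0.31 (SE 0.21, adjusted p = 0.565), with 0.19 and 0.021 in the common run.

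The S-phase median was 0.16 over 37 genes (camera, adjusted p = 0.00259, and adjusted p = 0.724 with an estimated correlation), with no member passing over all genes or adjusted over the list alone. In the common run it was 0.047, where camera placed the list lower (adjusted p = 0.917), and without antibiotics replicate 3 it was 0.046 (adjusted p = 0.531). The G2/M median was 0.18 over 31 genes (adjusted p = 0.00119, and adjusted p = 0.724 with an estimated correlation), and again no member passed over all genes or adjusted over the list alone. It was -0.037 in the common run (adjusted p = 0.428), 0.072 without re-fed replicate 1 (adjusted p = 0.14) and 0.067 without antibiotics replicate 3 (adjusted p = 0.509).

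Crypt-base stem cell and Wnt target genes had a median of 0.18 over 19 genes, 14 of them above 0 (camera, adjusted p = 0.00699, and adjusted p = 0.724 with an estimated correlation). Myb differed by 0.51 (SE 0.15), Msi1 by 0.33 (SE 0.11) and Smoc2 by 0.31 (SE 0.11), and no member passed over all genes or adjusted over the list alone. The median in the common run was 0.14 (adjusted p = 0.0366, and adjusted p = 0.68 with an estimated correlation), and the call was lost without re-fed replicate 3 (0.033, adjusted p = 0.125) and without antibiotics replicate 3 (0.094, adjusted p = 0.0772).

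**Figure D2:**
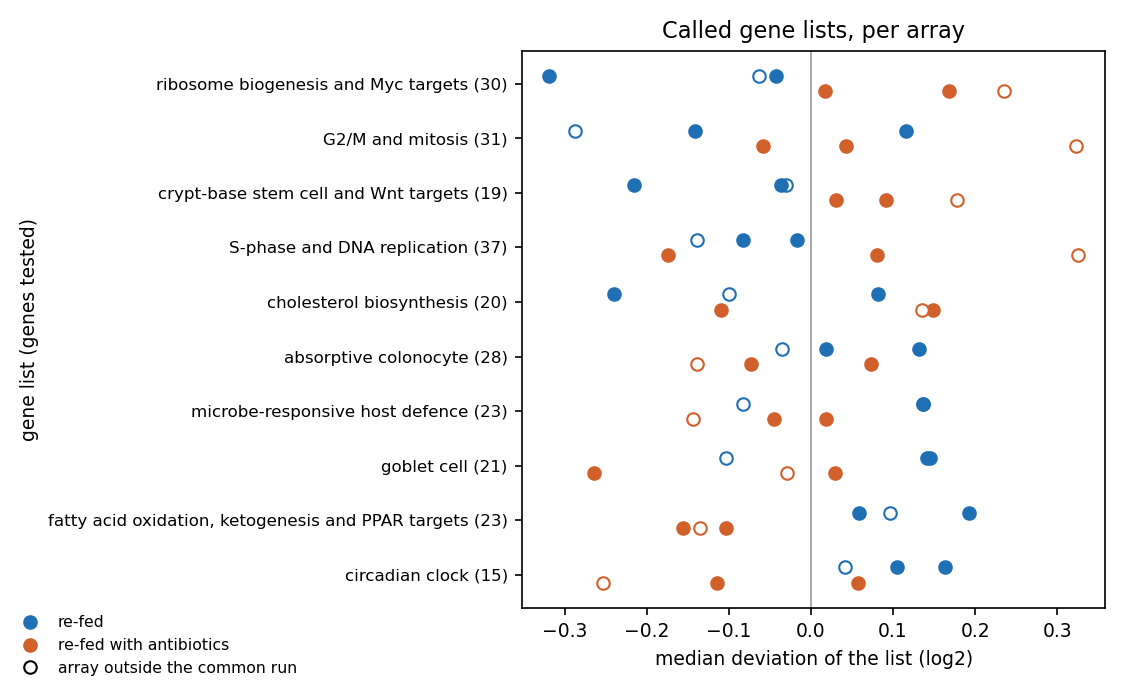
The plot shows, for each of the 10 called lists (vertical axis, genes tested in parentheses), the median over the list of log2 expression minus each gene's mean over 6 arrays (horizontal axis), 1 symbol per array, re-fed in blue and re-fed with antibiotics in orange, open for the 2 arrays outside the common run. Fatty acid oxidation genes separate the groups, at -0.16 to -0.10 with and 0.058 to 0.19 without antibiotics, whereas the G2/M list reaches 0.12 in a re-fed array and 0.32 in antibiotics replicate 3.

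Circadian clock genes had a median of -0.36 over 15 genes, 10 of them below 0. Dbp, a transcription factor driven by the clock, stood at 9.09 ± 0.58 without and 7.48 ± 0.36 with antibiotics (-1.61, SE 0.28, adjusted p = 0.0779), and its paralog Tef differed by -0.54 (SE 0.11) and the cell cycle kinase Wee1 by -0.52 (SE 0.12). No member passed over all genes, and 6 passed when adjusted over the list alone, all lower. Camera called the list (adjusted p = 0.0123), but not with an estimated correlation (adjusted p = 0.724), nor in the common run (-0.20, adjusted p = 0.0774), nor without antibiotics replicate 3 (-0.27, adjusted p = 0.0762).

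**Figure D3:**
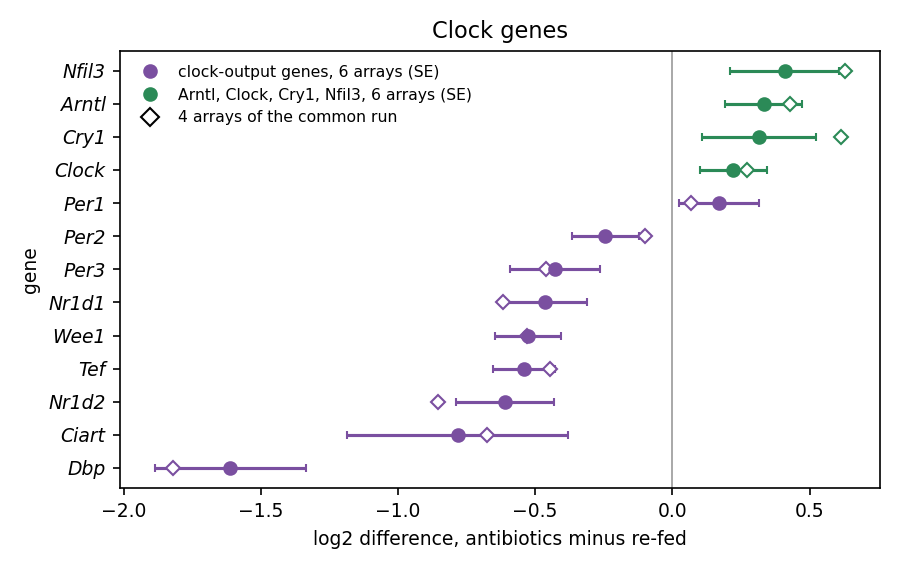
The plot shows the log2 difference, antibiotics minus re-fed (horizontal axis), of 13 clock genes (vertical axis), with filled circles and SE bars for 6 arrays and open diamonds for the 4 arrays of the common run. These are 13 of the 15 clock genes tested, and the rest were in neither group. The division was made after the list had been tested. The group labelled clock-output genes also holds Per genes, Nr1d genes and Ciart, which belong to the clock's own feedback loop. Of these 9 genes 8 lie below 0, down to -1.61 for Dbp. The 4 others, Arntl, Clock, Cry1 and Nfil3, lie between 0.22 and 0.41.

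Of 20 genes of xenobiotic metabolism, Abcb1a fell and 19 did not pass over all genes. Cyp2c55, a cytochrome P450 of the colon, stood at 12.21 ± 0.28 without and 10.88 ± 0.35 with antibiotics (-1.33, SE 0.19, adjusted p = 0.0584) and passed within the common run (-1.29, adjusted p = 0.0156). Cyp2c65 differed by -0.94 (SE 0.26). Adjusted over the list alone, 3 passed, all lower. The list itself had a median of -0.068 and was not called (adjusted p = 0.105). It was called lower in the common run (-0.12, adjusted p = 0.0189, and adjusted p = 0.68 with an estimated correlation), without re-fed replicate 1 (-0.12, adjusted p = 0.027), with array weights (-0.17, adjusted p = 0.0174) and with the deposited scaling over 6 arrays (-0.23, adjusted p = 0.000221) or in the common run (-0.17, adjusted p = 0.0188). The median was -0.00059 without re-fed replicate 3 (adjusted p = 0.233), -0.035 without antibiotics replicate 1 (adjusted p = 0.235) and 0.0042 with no filter on dim probe sets (adjusted p = 0.161), and that over 6 arrays lay at percentile 11.14 of 10000 random lists matched on mean expression.

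Cholesterol biosynthesis genes had a median of 0.15 over 20 genes, 16 above 0 (camera, adjusted p = 0.0414, and adjusted p = 0.767 with an estimated correlation), which turned to -0.025 with the deposited scaling and to -0.016 with that scaling in the common run, where camera still placed the list higher (adjusted p = 0.295 and 0.826). Insig1 differed by 0.39 (SE 0.20), Nsdhl by 0.26 (SE 0.14) and Lss by 0.32 (SE 0.17), and no member passed over all genes or adjusted over the list alone. The call was lost in the common run (0.076, adjusted p = 0.288), without re-fed replicate 1 (0.12) or 2 (0.11), and without antibiotics replicate 1 (0.12) or 3 (0.09). It was also lost with arrays centred on their medians (0.12, adjusted p = 0.313) or on all annotated probe sets (0.013, adjusted p = 0.277), and with the mean of a gene's probe sets (0.15, adjusted p = 0.0542).

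Interferon-stimulated genes differed between single arrays of the antibiotics group. Their median was -0.19 over 25 genes, 21 below 0, and the list was not called (adjusted p = 0.237), with Mx1 at -0.37 (SE 0.15), Oas1a at 0.31 (SE 0.15) and Psmb8 at -0.25 (SE 0.14). The list's deviation from the 6-array mean was -0.67, -0.15 and 0.59 in antibiotics replicates 1, 2 and 3, against 0.043 to 0.16 in the re-fed arrays. It was called lower in the common run (-0.55, adjusted p = 1.12e-07, and adjusted p = 0.68 with an estimated correlation) and without antibiotics replicate 3 (-0.55, adjusted p = 1.22e-10), and higher without antibiotics replicate 1 (0.15, adjusted p = 0.03). Array weights, which favour antibiotics replicate 1, also called it lower (-0.64, adjusted p = 4.14e-07), as did the deposited scaling over 6 arrays (-0.32, adjusted p = 0.000738) and in the common run (-0.59, adjusted p = 2.62e-06). Of the list for antigen presentation on MHC class II, 4 genes were tested, too few for the list test, with Cd74 at -0.47 (SE 0.16), Ifi30 at 0.27 (SE 0.12) and H2-Eb1 at -0.075 (SE 0.12), and none passed.

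The lists for amino acid response, chaperones, p53 targets and immediate-early genes were not called, and none of their members passed over all genes. Genes of the amino acid response and serine synthesis had a median of 0.039 over 24 genes (adjusted p = 0.381) and 0.10 in the common run, with Ddit4 at 0.50 (SE 0.13), Vldlr at -0.43 (SE 0.12) and Shmt2 at 0.43 (SE 0.17). Chaperones of the endoplasmic reticulum had a median of -0.033 over 22 genes and a mean of 0.00025 (adjusted p = 0.995), with a median of -0.049 in the common run, with Herpud1 at 0.28 (SE 0.10), Dnajb11 at -0.18 (SE 0.10) and Sel1l at -0.18 (SE 0.13). For p53 targets and apoptosis the median was -0.039 over 15 genes and the mean -0.03, although camera placed the list higher (adjusted p = 0.996). In the common run the median was 0.076, where camera placed it lower (adjusted p = 0.599). The ubiquitin ligase Mdm2 differed by -0.69 (SE 0.16) and was the 1 member of that list to pass when adjusted over the list alone, with Aen at 0.33 (SE 0.11) and Phlda3 at 0.44 (SE 0.15). Tnfsf10, named after its values were seen, passed over all genes in the common run (-0.78, adjusted p = 0.0398). Over 6 arrays it differed by -0.37 (SE 0.28, adjusted p = 0.61). Immediate-early genes, which respond to tissue handling, had a median of 0.014 over 23 genes (adjusted p = 0.845) and 0.13 in the common run (adjusted p = 0.0774), with Rhob at -0.45 (SE 0.13), Ccn1 at 0.75 (SE 0.26) and Klf4 at -0.28 (SE 0.13).

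Markers of rarer epithelial cell types gave no call over 6 arrays. Enteroendocrine genes had a median of -0.039 over 11 genes (adjusted p = 0.866), with Tph1, which makes serotonin, at -0.46 (SE 0.13), Tac1 at -0.30 (SE 0.12) and Pcsk1 at 0.25 (SE 0.18). The list's deviation from the 6-array mean was -0.057, -0.45 and 0.43 in antibiotics replicates 1, 2 and 3, against -0.087 to 0.087 in the re-fed arrays. Its median was -0.26 in the common run (adjusted p = 0.0676), -0.28 without antibiotics replicate 3 (adjusted p = 0.0605) and 0.23 without antibiotics replicate 2 (adjusted p = 0.447). Tuft cell genes had a median of -0.16 over 10 genes (adjusted p = 0.28) and -0.082 in the common run (adjusted p = 0.0801), with Alox5 at -0.39 (SE 0.11), Trpm5 at -0.34 (SE 0.17) and Spib at 0.54 (SE 0.29), and were called lower without re-fed replicate 1 (-0.19, adjusted p = 0.0373).

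The genes of the sort differed between the groups by less than their error. Epcam stood at 12.16 ± 0.11 without and 12.12 ± 0.06 with antibiotics (-0.036, SE 0.10, adjusted p = 0.916). Ptprc lay below the floor in both, at 5.44 ± 0.11 and 5.40 ± 0.12. The pan-epithelial list had a median of -0.069 over 17 genes, -0.022 in the common run, and was not called (adjusted p = 0.125), with Cdx2 at -0.32 (SE 0.11), Cdx1 at 0.33 (SE 0.12) and the keratin Krt18 at -0.59 (SE 0.094, adjusted p = 0.0692), the 1 member that passed when adjusted over the list alone.

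Most markers of other cells lay below the floor. Of 24 T cell and intraepithelial lymphocyte genes 5 were tested (median 0.046, adjusted p = 0.695, and 0.077 in the common run), with Ccl5 at 0.24 (SE 0.14), Thy1 at 0.17 (SE 0.12) and Cd3e at -0.15 (SE 0.16). Of 18 B and plasma cell genes 6 were tested (median 0.032, adjusted p = 0.881, and 0.099 in the common run), with Pou2af1 at 0.17 (SE 0.12), Pax5 at -0.15 (SE 0.11) and Cd79b at 0.11 (SE 0.13). Of 24 myeloid genes 4 were tested, too few for the list test, with Cd14 at 0.30 (SE 0.18), Lst1 at 0.23 (SE 0.20) and Cx3cr1 at -0.026 (SE 0.11). Stroma and endothelium gave a median of 0.077 over 10 genes (adjusted p = 0.878) and 0.13 in the common run, with Pecam1 at -0.44 (SE 0.17), Lyve1 at -0.17 (SE 0.096) and Acta2 at 0.20 (SE 0.14). Small-intestinal enterocyte and Paneth cell genes gave a median of 0.076 over 12 genes (adjusted p = 0.28) and 0.21 in the common run (adjusted p = 0.0774), with Onecut2 at 0.27 (SE 0.11), Rbp2 at 0.31 (SE 0.13) and Dpp4 at 0.23 (SE 0.11). No gene of these 5 lists passed, over all genes or adjusted over the list alone. In the common run with the deposited scaling, camera called the T cell list (0.18, adjusted p = 0.0425) and the small-intestinal list (0.16, adjusted p = 0.0448) higher.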

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

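Chosen after seeing the data were the centring on all annotated probe sets and both settings with the common run. The deposited scaling had been the planned main setting, which quantile normalisation replaced, and is given as an alternative. The 7 genes called (1 higher, 6 lower) became 2 (1 and 1) with no filter on dim probe sets, which tests more genes, 43 (8 and 35) with a stricter filter, which tests fewer, 43 (7 and 36) with an intensity trend and robust eBayes, and 1169 (502 and 667) with array weights. They became 45 (3 and 42) with the deposited scaling, 62 (4 and 58) with arrays centred on all annotated probe sets, 54 (13 and 41) in the 4 arrays of the common run and 63 (6 and 57) there with the deposited scaling. With all probe sets tested on their own there were 3 (1 and 2), at an absolute log2 difference of at least 1 there were 4 (1 and 3), and at an adjusted p under 0.10 there were 50 (10 and 40). The median of all genes was -0.12 with the deposited scaling and 0.0033 after quantile normalisation. The share called higher was 14.3%, and 42.9% with array weights, which gave antibiotics replicate 1 a weight of 3.82 and antibiotics replicate 3 a weight of 0.33. Leaving out 1 array gave 0 (antibiotics replicate 1) to 11 genes (re-fed replicate 3), 0 to 2 higher and 0 to 10 lower. All 7 genes were among those called with the stricter filter, the trend, array weights, the mean of probe sets and the common run. The same held with the deposited scaling and the centring on all annotated probe sets. Over their 18 alternatives none changed sign.

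The 10 lists called became 0 with an estimated correlation and 0 with fry, and 4 to 10 with 1 array left out (4 without antibiotics replicate 3). The S-phase median of 0.16 was 0.046 to 0.27 with 1 array left out, 0.047 in the common run and 0.065 there with the deposited scaling, and it stayed at 0.16 but uncalled with an estimated correlation and with fry. The G2/M median of 0.18 was 0.067 to 0.30 with 1 array left out, 0.017 with array weights, -0.037 in the common run and 0.0020 there with the deposited scaling, and it stayed at 0.18 but uncalled with an estimated correlation and with fry. The cholesterol list turned to -0.025 with the deposited scaling and -0.016 with that scaling in the common run, and the interferon list of -0.19 went to 0.15 without antibiotics replicate 1 and to -0.55 without antibiotics replicate 3. Apart from what is described here, the cause was not tested.

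With the replicate block, 7 genes were called (1 higher, 6 lower), 3 of them shared with the fit without it, and 10 lists. Same-numbered samples deviated together with correlations of 0.021, -0.034 and -0.22 across genes, which gave no sign of pairing by number. Re-fed replicate 3 correlated best with antibiotics replicate 2 (0.24). With 3 samples per group, and deviations taken from each group's own mean, these values cannot exclude pairing. No detection call or background is given for these arrays, so what dim signal limits is known only through the filter.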

Other observations

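Genes that passed within the 4 arrays of the common run, named here after their values were seen, included further transporters and enzymes. The neutral amino acid transporter Slc6a19 differed by 1.30 (SE 0.14, adjusted p = 0.0248) there and by 1.19 (SE 0.22, adjusted p = 0.0947) over 6 arrays. The metallothionein Mt1 differed by 1.94 (SE 0.30) and 1.38 (SE 0.34), and Sptssb, a subunit of serine palmitoyltransferase, by -1.93 (SE 0.25) and -1.86 (SE 0.27). Of the aldo-keto reductases, Akr1c18 (-0.98, SE 0.13) and Akr1c19 (1.23, SE 0.15) also passed there, besides Akr1b8 and Akr1b10. The family as a whole, 3 genes higher and 7 lower, was not called over 6 arrays (adjusted p = 0.314). Duoxa2, which matures the epithelial oxidase Duox2, differed by -1.18 (SE 0.18) in the common run and -0.97 (SE 0.32, adjusted p = 0.281) over 6 arrays.

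Of 151 gene families defined by shared symbols after the lists had been tested, camera called 3, each also in the common run, and none over 6 arrays with an estimated correlation (adjusted p = 0.978 for all 3). Ribosomal protein genes had a median difference of 0.19, with 55 of 61 above 0 (adjusted p = 6.19e-07). Collagen genes had a median of 0.14 over 37 genes (adjusted p = 0.00418) and microRNA genes a median of 0.16 over 83 (adjusted p = 0.0014), at mean log2 levels of 6.52 and 6.87 against 7.87 over all genes tested. In the common run camera also called the families Krtap (median 0.30, adjusted p = 0.00569), Nkx (0.19, adjusted p = 0.0486) and Olfr (0.14, adjusted p = 0.0486). Their mean log2 levels were 6.86, 6.50 and 6.39. Whether a shift of dim signal lies behind these calls was not tested. Of 13768 probe sets that name several genes or none here, 5841 lay above the floor, and limma called 0 of them, with 554 at an unadjusted p under 0.05.

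Of the tests that follow, those of separate RMA runs, of differences between samples of one group and of the contrast between clock genes were chosen only after the result was seen. The first pattern is the higher S-phase and G2/M lists. Their 68 genes together had a median of 0.17 over 6 arrays and 0.0041 in the common run, which is consistent with a share of the shift that comes from arrays of separate RMA runs. Differences between samples of one group, which need not be single mice, were examined as well. Taken gene by gene over the G2/M list, the median difference between the re-fed arrays of the common run was 0.28. That is more than the 6-array shift of 0.18, while between the antibiotics arrays there it was 0.075. An effect of antibiotics on proliferation stays open and untested beyond this.

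The second pattern is the lower level with antibiotics of the 9 genes grouped as clock output. The group also holds Per genes, Nr1d genes and Ciart, which belong to the clock's own feedback loop. Separate RMA runs are argued against for these 9 output genes, since their median was -0.53 in the common run and -0.52 over 6 arrays. The whole clock list had a median of -0.36 over 6 arrays and -0.20 in the common run, where it was not called (camera, adjusted p = 0.0774). A difference in clock phase at dissection remained possible: Arntl, Clock, Cry1 and Nfil3, which peak at other hours than Dbp, had a median of 0.32, as such a difference would need. The mean of these 4 minus the mean of the 9 output genes was 0.44 ± 0.21 with and -0.44 ± 0.41 without antibiotics (SD, n = 3), with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. Whether phase followed the antibiotics, the time of feeding or the hour of dissection cannot be read from these labels, which give no clock time.

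The third pattern is the lower level of fatty acid oxidation genes. Separate RMA runs are argued against by the median of -0.27 in the common run, against -0.26 over 6 arrays. A trend with expression level is argued against too, since the list's median lay at percentile 0 of 10000 random lists matched on mean expression. A response of these genes to antibiotics is a hypothesis that stays open, found and tested on the same data.

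The 6 arrays divide into 3 and 3 in 10 ways, too few for a share under 0.05. The true division called 7 genes and the highest other 0, so that 1 of 10 reached the count, whereas for gene lists the true division called 10 and the highest other also 10, so that 2 of 10 did. That other division sets re-fed replicate 1 and antibiotics replicates 1 and 2 against the rest. Within the common run it is the comparison by treatment itself, so it is not a division free of treatment. Nor is any other, since each sets 2 arrays of a group against 2 of the other. For single lists, the p in the true division and the smallest in the others were 3.25e-08 and 0.000164 for fatty acid oxidation, 0.00389 and 0.00138 for the circadian clock, 0.00054 and 1.98e-17 for S phase, and 0.000149 and 4.56e-21 for G2/M.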
